A study of Arabidopsis thaliana with 30 samples.

How the data were processed

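Transcript levels were measured in shoots and roots of Arabidopsis thaliana seedlings on Affymetrix arrays, with 30 arrays in 10 groups of 3 and 5 groups per tissue. Groups and replicate numbers were taken from the sample titles, which call the replicates biological; p-values measure the spread between these samples. The values were deposited by the authors as log2 expression, made with RMA per the file headers. The submitters' processing notes name MAS5 instead. The values, which ran from 3.00 to 14.0 in shoots and from 3.50 to 13.8 in roots, were used as RMA log2 values. The version of the normalization tool is not given in the sources used here. Medians ran from 6.61 to 6.76 in the 15 shoot arrays and from 6.92 to 7.08 in the 15 root arrays. The 2 tissues were deposited as separate tables and treated as normalized separately, so no fold change was tested between tissues; the closing section holds 1 ratio of root to shoot levels, with this limit. The same tables hold log2 fold changes, p-values, Benjamini-Hochberg values and q-values of the authors' own tests, per the file headers. The deposited fold change of the overexpressor is wild type minus overexpressor. All fold changes given here were recomputed as overexpressor minus wild type.

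Probe sets were named through the locus column of the deposited tables, with symbols from a reference table of assembly TAIR10.1. Of 22746 probe sets, 21452 had 1 gene, 1110 several genes and 184 none. Of the probe sets with 1 gene, 21278 matched the reference table and stood for 21227 genes; no gene was named from a probe set with several, and the largest changes given are those among probe sets with 1 gene. The files used hold no detection calls. Probe sets whose mean over the 15 arrays of a tissue lay at or above the 30th percentile were tested, which left 15922 per tissue, with 15098 genes in shoots and 15086 in roots. A gene with several probe sets was represented by the single-gene probe set with the highest mean.

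Limma 3.58.1 in R 4.3.3 was fitted to the 15 arrays of each tissue with a mean per group, so that all 5 groups shared the estimate of the spread. Moderated tests with an intensity trend were two-sided, and p-values were adjusted by the Benjamini-Hochberg method over the probe sets tested, with a threshold of 0.05. The comparisons were nitrogen starvation (starved against sufficient wild type), AtNIGT1.2 overexpression (overexpressor against wild type, both starved), AtNIGT1.2-VP induction (estradiol against mock in the VP line) and, as background, the mock-treated VP line against sufficient wild type. Each ± is a standard error of the fit unless SD is named. A rank or permutation test of 3 against 3 arrays cannot give an exact p under 0.10, so none was used for single genes.

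Gene lists, the rule for named genes and the main settings were fixed before the data were examined. The 22 lists held 361 loci, of which 323 had a single-gene probe set. They covered the NIGT1 family, nitrate transport, ammonium, urea and amino acid transport, nitrate assimilation, glutamine and glutamate metabolism, nitrogen response regulators, nitrogen demand peptides, phosphate starvation, iron starvation, sulfur starvation, photosynthesis, anthocyanin and flavonoid synthesis, senescence and autophagy, starch and sugar, cytokinin, abscisic acid and cold, defence, heat shock, xenobiotic response, root hair markers, root tissue markers and reference genes. Lists with at least 5 measured members were tested with camera at a preset correlation of 0.01, adjusted by the Benjamini-Hochberg method over the lists tested, and again with an estimated correlation. Counts of members past the threshold were also adjusted over the list alone; these equalled the counts over all probe sets except where both are given. The named genes were the 8 highest and the 8 lowest log2 fold changes among genes past the threshold whose 3 values in one group all lay above or all below those of the other. The 4 NIGT1 genes, NRT2.1, NRT2.4, NRT2.5, NPF6.3, NIA1, NIA2 and NIR1 were named in every comparison. Up to 4 members of each list with the smallest adjusted p were added, with the 12 genes per tissue that were lower in the overexpressor and higher with AtNIGT1.2-VP by the largest margin. Chance alone gives non-overlapping groups of 3 and 3 for 10% of genes.

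Overlaps of calls were set against independent lists of the same sizes with a hypergeometric test, 1 probe set per gene. Nitrogen starvation and overexpression share the 3 arrays of starved wild type in each tissue, so unchanged groups were simulated against them 20 times. The AtNIGT1.2-VP comparison shares no array with either.

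The fits were tested on simulated data with the 15922 probe sets of each tissue and 200 changed. For each of the 8 comparisons, 61 to 88% of changes of 0.5 on the log2 scale and 92 to 99% of changes of 1 were recovered, and 3.14 to 9.55% of calls were false. For the list tests, all measured photosynthesis genes were shifted by 0.3 and no other gene was changed. The shifted list was called in 6 of 6 simulated list tests and no other list was. In the real comparisons with list tests 38.1 to 54.8% of probe sets changed, so list calls amid such wide change were not tested. Simulated genes varied independently of each other, so false calls from genes that vary together were not tested. In the real data, groupings of 3 and 3 arrays that mixed the 2 groups called up to 11 lists in shoots and 12 in roots. Such groupings keep part of the real difference, so these counts do not measure false calls. Of 100 genes made lower in one comparison and higher in the other, 93 were found in shoots and 99 in roots.

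The alternatives tried were no filter and a filter at the 50th percentile, the replicate number as a block, a second quantile normalization, the values of the series matrix, a variance estimate without the trend, a fit of only the 2 groups compared, a minimum log2 fold change of 1, an estimated correlation in camera and each array left out in turn. The authors' deposited p-values were added as an alternative after the data had been seen. They come from Welch tests over all 22746 probe sets, so their counts differ from those given here in both test and probe sets. Pseudocounts were not varied because the values were already on a log scale. An effect of tissue on a response was not tested. No column of another sample was present in the tables.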

Results

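Expression was profiled in 10-day-old Arabidopsis thaliana seedlings, with shoots and roots on separate arrays, to find target genes of AtNIGT1.2, a member of the NIGT1 subfamily of GARP-type transcription factors. Wild type Col-0 seedlings and an AtNIGT1.2 overexpressor were moved at 7 days to plates with 5 mM ammonium nitrate (sufficient, wild type only) or with no nitrogen source (starved) for 3 days. A line carrying an estradiol-inducible AtNIGT1.2-VP fusion, an abbreviation that the labels do not spell out, was moved at 9 days to plates with 5 mM ammonium nitrate, with or without estradiol, for 24 h. Each of the 5 groups had 3 arrays per tissue. Arrays of a group correlated across probe sets with r of 0.994 to 0.998 in shoots and 0.996 to 0.999 in roots. The first principal component held 50.2% of the variance in shoots and 54.8% in roots.

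The AtNIGT1.2 transcript was highest in the overexpressor and in the induced VP line. In shoots its level was 13.88 ± 0.08 (log2, mean ± SD, n = 3) in the overexpressor against 7.26 ± 0.84 in starved wild type, 98.5-fold apart. Estradiol raised it from 9.56 ± 0.08 to 12.50 ± 0.13, or 7.66-fold. In roots the overexpressor reached 13.67 ± 0.08 against 7.81 ± 0.08, 58.1-fold apart, and estradiol raised the level from 9.21 ± 0.04 to 13.33 ± 0.05. The overexpressor levels lay at the top of the scale, where the highest values of those arrays began at 13.90 in shoots and at 13.68 in roots, so a saturated signal would make both folds too small. The probe set does not tell the transgene from the endogenous transcript. Without estradiol the VP line differed from sufficient wild type by -0.20 ± 0.25 in shoots (adjusted p = 0.565) and by 0.28 ± 0.06 in roots (adjusted p = 0.0019).

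**Figure D1:**
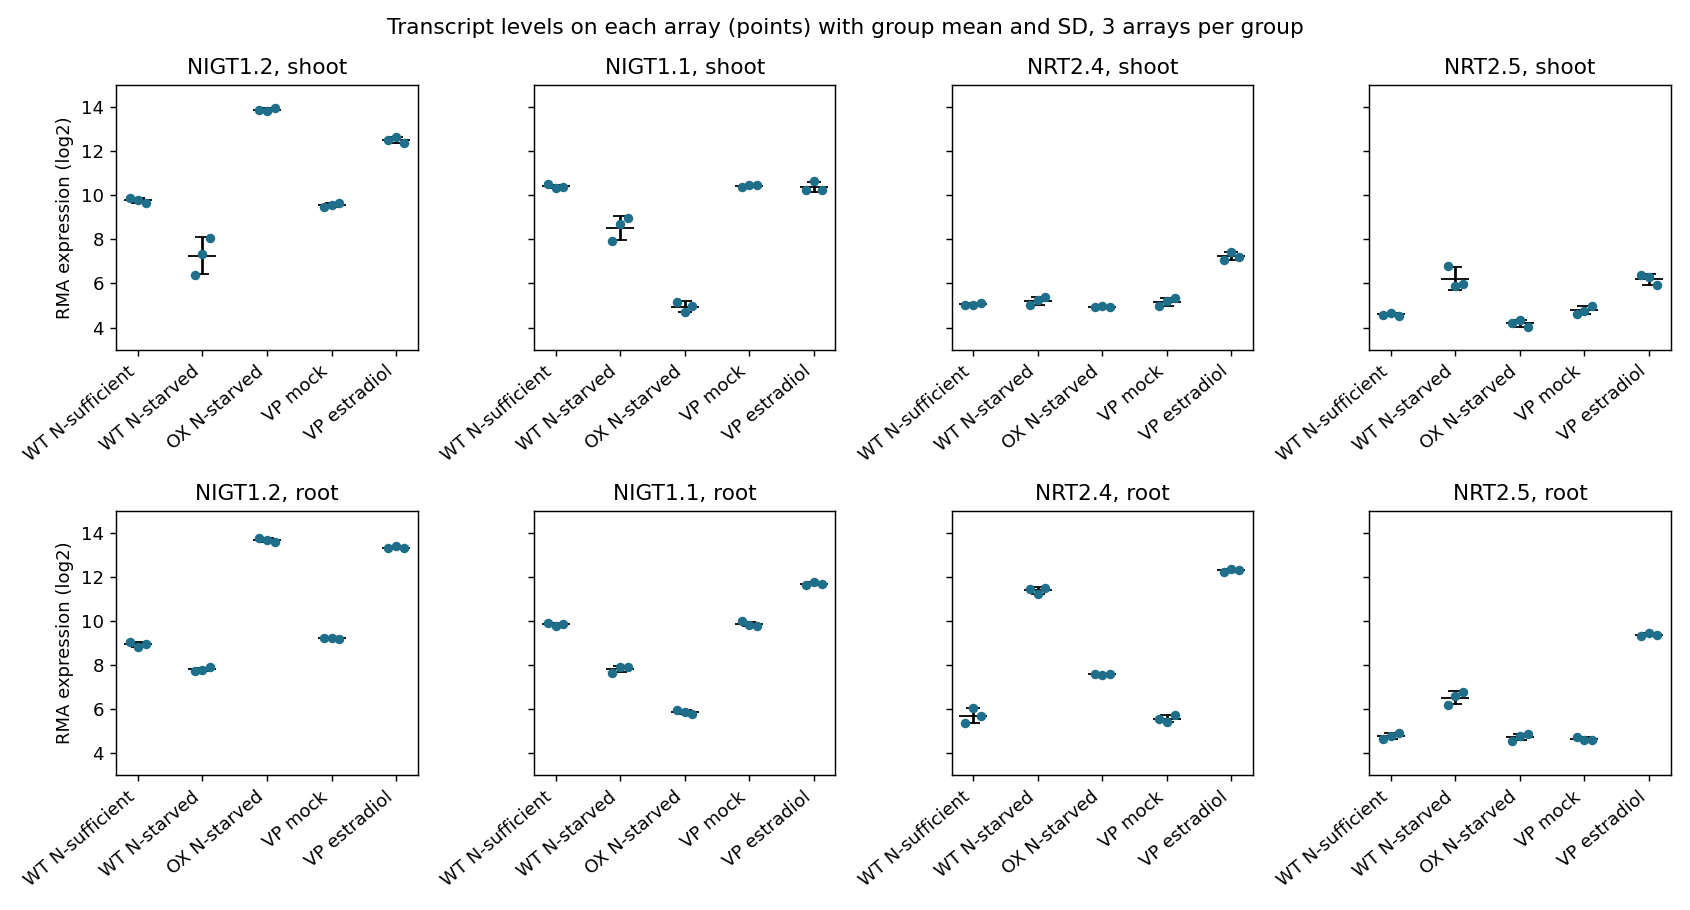
RMA expression (log2) of NIGT1.2, NIGT1.1, NRT2.4 and NRT2.5 on each array in the 5 groups of shoots (upper row) and roots (lower row); points are arrays and bars are group means ± SD of 3 arrays. Root NRT2.4 lay at 11.38 in starved wild type, 7.58 in the overexpressor and 12.29 in the induced VP line.

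With nitrogen starvation of wild type shoots, most measured genes of nitrate assimilation and photosynthesis fell, and most of those of ammonium and amino acid transport, senescence and flavonoid synthesis rose. The largest rise was that of PAP2, a MYB activator of anthocyanin synthesis, at 4.79 ± 0.21 on the log2 scale (27.7-fold, adjusted p = 1.54e-10). It was followed by AT1G80130 (3.96 ± 0.16), the lipid transfer protein gene LTP4 (3.95 ± 0.83), the cytosolic glutamine synthetase gene GLN1;4 (3.79 ± 0.16) and the borate transporter family gene BOR5 (3.75 ± 0.16). LTP3 (3.52 ± 0.66), AT5G39520 (3.51 ± 0.36) and AT4G33040 (3.39 ± 0.16) came next. The first sufficient array stood apart for LTP4 and LTP3, which rose by 5.51 ± 0.34 and 4.70 ± 0.33 without it, and by 2.92 ± 0.75 and 2.54 ± 0.51 without the second. The deepest fall was that of ASN1, encoding an asparagine synthetase, at -5.62 ± 0.47 (adjusted p = 9.64e-08). BT2, a BTB/TAZ protein of nitrogen response, fell by 4.29 ± 0.30, AT4G15690 by 3.85 ± 0.14, the phosphodiesterase gene GDPD2 by 3.70 ± 0.30 and AT2G20670 by 3.52 ± 0.34. Falls were also seen for the myo-inositol oxygenase gene MIOX2 (-3.51 ± 0.40) and for LBD38 (-3.41 ± 0.17) and LBD39 (-3.23 ± 0.19), nitrogen-responsive repressors of anthocyanin synthesis.

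Among the genes followed throughout, the nitrate reductase genes NIA1 (-2.43 ± 0.17) and NIA2 (-0.50 ± 0.07) fell in starved shoots. So did the nitrite reductase gene NIR1 (-1.66 ± 0.10). NIGT1.1 (-1.88 ± 0.20), NIGT1.2 (-2.51 ± 0.25) and NIGT1.4 (-2.03 ± 0.17) fell. NIGT1.3 lay below the filter. The nitrate transporter genes NRT2.1 and NRT2.5 rose by 0.90 ± 0.28 and 1.62 ± 0.19; without the third starved array NRT2.1 did not pass (adjusted p = 0.0733). NRT2.4 (0.15 ± 0.12, adjusted p = 0.311) and NPF6.3 (0.12 ± 0.13, adjusted p = 0.476) did not pass the test.

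In the gene lists, 13 of 16 ammonium, urea and amino acid transporters rose and 0 fell in starved shoots, among them the urea transporter DUR3 (3.00 ± 0.16), AAP4 (2.00 ± 0.11) and LHT1 (2.03 ± 0.15). The list was called by camera (adjusted p = 6.78e-07, and adjusted p = 0.0543 with an estimated correlation). Of 21 senescence and autophagy genes 18 rose and 1 fell, led by the NAC factor NAP (2.24 ± 0.17) and the chlorophyll breakdown genes PAO (1.18 ± 0.09) and NYE1 (1.84 ± 0.17), at adjusted p = 8.16e-06 and adjusted p = 0.157 with an estimated correlation. Anthocyanin and flavonoid genes rose in 10 of 18 cases and fell in 1, with TT19 at 2.93 ± 0.25 and DFR at 3.08 ± 0.28 (adjusted p = 0.00278, and adjusted p = 0.367 with an estimated correlation). Of 29 photosynthesis genes 18 fell and 0 rose, or 22 and 0 adjusted over the list alone; GUN4 fell by 0.92 ± 0.09 and CHLM by 0.77 ± 0.09 (adjusted p = 1.86e-05, and adjusted p = 0.367 with an estimated correlation). Nitrate assimilation genes fell in 10 of 15 cases and rose in 3 (adjusted p = 0.00944, and adjusted p = 0.367 with an estimated correlation). The NIGT1 family fell in 4 of 6 cases, with HHO5 at -1.60 ± 0.13 (adjusted p = 0.0149, and adjusted p = 0.276 with an estimated correlation).

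Cytokinin genes fell in 8 of 15 cases and rose in 3 in starved shoots, led by the type-A response regulators ARR7 (-2.22 ± 0.12), ARR6 (-3.22 ± 0.18) and ARR9 (-1.80 ± 0.11), at adjusted p = 0.0149 and adjusted p = 0.157 with an estimated correlation. Of 7 nitrogen demand peptide genes 5 rose and 1 fell, with the glutaredoxin-like shoot-to-root signals CEPDL2 at 3.38 ± 0.16 and CEPD2 at 2.36 ± 0.11 (adjusted p = 0.00944, and adjusted p = 0.13 with an estimated correlation). Abscisic acid and cold genes rose in 8 of 9 cases, with ABI1 at 1.37 ± 0.16 and RD29A at 1.71 ± 0.33 (adjusted p = 0.00278, and adjusted p = 0.367 with an estimated correlation). All 6 xenobiotic response genes rose, with CYP81D8 at 2.07 ± 0.18 (adjusted p = 0.000287, and adjusted p = 0.157 with an estimated correlation). Lists without a call included nitrate transport (11 of 24 rose, 2 fell), glutamine and glutamate metabolism (10 of 16 rose, 6 fell), nitrogen regulators (4 of 18 rose, 7 fell) and phosphate starvation (10 of 23 rose, 4 fell). The others were sulfur starvation (4 of 9 rose, 1 fell), starch and sugar (4 of 7 rose, 2 fell), defence (6 of 11 rose, 0 fell), root tissue markers (1 of 5 rose, 1 fell) and reference genes (2 of 8 rose, 1 fell). For glutamine and glutamate metabolism, nitrogen regulators, root tissue markers and reference genes, the median, the mean and the camera direction differed in sign.

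Over all probe sets, 4433 were higher and 4182 lower in starved shoots at an adjusted p under 0.05 by limma with Benjamini-Hochberg adjustment, of 15922 tested, and 768 and 491 of these changed by at least 1 on the log2 scale. The authors' deposited table called 2868 by Benjamini-Hochberg values and 8377 by q-values. With an estimated correlation 0 of the 10 called lists kept an adjusted p under 0.05.

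In starved wild type roots, most measured genes of nitrate assimilation and of ammonium, urea and amino acid transport rose, and most photosynthesis genes fell. CEPH, a CEPD-induced phosphatase of the nitrate uptake pathway, rose by 5.83 ± 0.14 (56.8-fold, adjusted p = 6.26e-18) and the high-affinity nitrate transporter gene NRT2.4 by 5.67 ± 0.12 (51.1-fold, adjusted p = 8.41e-19). Next came AT5G04120 (3.73 ± 0.12), the cytochrome P450 gene CYP716A2 (3.67 ± 0.10), GLN1;4 (3.60 ± 0.10), the peptide gene CEP5 (3.55 ± 0.12), NRT2.1 (3.41 ± 0.13) and AT5G11930 (3.41 ± 0.10). The deepest falls were those of AT4G39675 (-5.17 ± 0.16), BT2 (-5.02 ± 0.12), AT1G49500 (-4.49 ± 0.09). Next were the amidotransferase gene GAT1_2.1 (-4.18 ± 0.13), the photorespiratory aminotransferase gene AGT (-4.00 ± 0.11), AT1G80440 (-3.94 ± 0.12), AT5G19120 (-3.89 ± 0.13) and AT2G16005 (-3.88 ± 0.15).

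Of the genes followed throughout, NIA1, NIA2 and NIR1 rose in starved roots, by 2.46 ± 0.11, 0.91 ± 0.05 and 0.83 ± 0.06. NRT2.5 rose by 1.73 ± 0.12, and NPF6.3, the dual-affinity nitrate transporter and sensor, fell by 1.36 ± 0.06. NIGT1.1 (-2.04 ± 0.07), NIGT1.2 (-1.13 ± 0.06) and NIGT1.4 (-2.1 ± 0.10) fell. NIGT1.3 rose by 0.39 ± 0.08 (adjusted p = 0.000273).

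Nitrate assimilation genes rose in 14 of 15 cases in starved roots and fell in 1, with G6PD3 at 1.38 ± 0.08 and RFNR2 at 0.91 ± 0.05 (adjusted p = 1.61e-06, and adjusted p = 0.154 with an estimated correlation). Of 15 ammonium, urea and amino acid transporters 12 rose and 1 fell, or 13 and 1 adjusted over the list alone, with AAP4 at 2.11 ± 0.09, AMT1;1 at 1.04 ± 0.05 and DUR3 at 1.80 ± 0.09; this call held with an estimated correlation (adjusted p = 1.61e-06, and adjusted p = 0.0279 with an estimated correlation). Photosynthesis genes fell in 25 of 26 cases, with RCA at -1.58 ± 0.07 and LHCB3 at -1.43 ± 0.07 (adjusted p = 1.31e-18, and adjusted p = 0.092 with an estimated correlation). All 7 root hair markers rose, with RHD6 at 1.39 ± 0.10 and PRP3 at 1.42 ± 0.12 (adjusted p = 0.00164, and adjusted p = 0.178 with an estimated correlation). Of 8 nitrogen demand peptide genes 6 rose and 2 fell (adjusted p = 0.0114, and adjusted p = 0.154 with an estimated correlation). The NIGT1 family fell in 4 of 7 cases and rose in 1, or 2 adjusted over the list alone (adjusted p = 0.00346, and adjusted p = 0.154 with an estimated correlation). Nitrogen regulators fell in 7 of 16 cases and rose in 4, with LBD39 at -2.95 ± 0.08 and LBD38 at -2.20 ± 0.07 (adjusted p = 0.0385, and adjusted p = 0.154 with an estimated correlation).

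Nitrate transport was not called as a list in starved roots, since 12 of 25 genes rose and 10 fell; NRT2.2 rose by 3.27 ± 0.11. Phosphate starvation genes rose in 8 of 23 cases and fell in 8, a list whose median and mean differed in sign, with RNS1, an S-like ribonuclease, at 3.06 ± 0.09 and GDPD1 at -1.40 ± 0.10. Sulfur starvation genes rose in 6 of 11 cases and fell in 2, with APR1 at 1.58 ± 0.08. Iron starvation genes rose in 2 of 6 cases and fell in 3, with the iron transporter IRT1 at -2.80 ± 0.15. Cytokinin genes rose in 5 of 20 cases and fell in 10, with CYP735A2, an enzyme of trans-zeatin synthesis, at -1.63 ± 0.10. Heat shock genes, too few for a list test, rose in 3 of 4 cases and fell in 1. Over all probe sets, 5265 were higher and 3466 lower of 15922 tested (limma, Benjamini-Hochberg), 408 and 433 of them by at least 1; the authors' deposited table called 2533 by Benjamini-Hochberg values and 8380 by q-values.

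In starved shoots of the overexpressor, most measured genes of phosphate starvation, photosynthesis and senescence were lower than in starved wild type. GLN1;4 fell by 5.03 ± 0.16 (adjusted p = 1.34e-12), the senescence factor NAP by 4.34 ± 0.17, the kinase gene CIPK20 by 4.07 ± 0.16, AT2G17710 by 4.07 ± 0.12. The urea transporter DUR3 fell by 4.02 ± 0.16, AT1G72920 by 3.91 ± 0.18 and RNS1 by 3.74 ± 0.20. ORA47, an AP2/ERF factor of the wound and jasmonate response, fell by 4.41 ± 0.30; it had risen by 1.74 ± 0.30 with nitrogen starvation in wild type, on the same starved arrays. Besides NIGT1.2 (6.62 ± 0.25), the largest rises were those of AT3G28220 (4.16 ± 0.29), the cold-regulated gene COR15A (3.38 ± 0.44) and JMJD5 (2.91 ± 0.14). Next were AT4G17470 (2.82 ± 0.20), the glucanase gene PR2 (2.74 ± 0.41), AT1G52000 (2.68 ± 0.15) and the lipoxygenase gene LOX2 (2.49 ± 0.14). JMJD5, a jumonji protein linked to the circadian clock, was also 2.58 ± 0.14 higher in mock-treated VP shoots than in sufficient wild type.

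NIGT1.1 fell by 3.57 ± 0.20 in overexpressor shoots, NRT2.5 by 2.02 ± 0.19, NIR1 by 1.22 ± 0.10, NIA2 by 0.86 ± 0.07 and NIA1 by 0.60 ± 0.17. NIGT1.4 (-0.12 ± 0.17), NRT2.1 (-0.60 ± 0.28), NRT2.4 (-0.26 ± 0.12) and NPF6.3 (-0.11 ± 0.13) did not pass the test, and NIGT1.3 lay below the filter. NRT2.1 passed without the third overexpressor or the second wild type array (-1.0 ± 0.22 and -0.79 ± 0.30), and NRT2.4 without the first wild type array (-0.36 ± 0.12).

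Phosphate starvation genes fell in 18 of 23 cases in overexpressor shoots and rose in 0, with SPX1 at -2.45 ± 0.14, PAP12 at -1.22 ± 0.09 and the acid phosphatase gene PAP17 at -2.13 ± 0.16 (adjusted p = 5.65e-10, and adjusted p = 0.00604 with an estimated correlation). Photosynthesis genes fell in 28 of 29 cases, with PSAD2 at -1.77 ± 0.11 and CHLH at -1.27 ± 0.09 (adjusted p = 1.65e-13, and adjusted p = 0.221 with an estimated correlation). Senescence and autophagy genes fell in 14 of 21 cases and rose in 0, with WRKY53 at -1.98 ± 0.17 and ORE1 at -2.19 ± 0.20 (adjusted p = 0.000145, and adjusted p = 0.221 with an estimated correlation). Sulfur starvation genes fell in 7 of 9 cases and rose in 1, with GGCT2;1 at -1.86 ± 0.10 and APR1 at -1.92 ± 0.14 (adjusted p = 0.000258, and adjusted p = 0.112 with an estimated correlation). Cytokinin genes fell in 8 of 15 cases and rose in 1, with ARR16 at -2.12 ± 0.17 and LOG7 at -1.35 ± 0.16 (adjusted p = 0.00495, and adjusted p = 0.112 with an estimated correlation). Glutamine and glutamate metabolism genes fell in 9 of 16 cases and rose in 2, or 9 and 3 adjusted over the list alone, with ASN3 at -1.63 ± 0.09 (adjusted p = 0.00609, and adjusted p = 0.112 with an estimated correlation). Flavonoid genes fell in 6 of 18 cases and rose in 0, with MYBL2 at -2.41 ± 0.13 (adjusted p = 0.00609, and adjusted p = 0.656 with an estimated correlation). Ammonium, urea and amino acid transporters fell in 7 of 16 cases and rose in 1, with AMT1;1 at -1.55 ± 0.10 (adjusted p = 0.0153, and adjusted p = 0.221 with an estimated correlation).

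Lists without a call in overexpressor shoots included the NIGT1 family, of which 3 of 6 members fell and 1, the transgene's own NIGT1.2, rose, or 4 and 1 adjusted over the list alone. Nitrate transport genes rose in 6 of 24 cases and fell in 6, with NPF7.3 at -1.70 ± 0.15 and NPF3.1 at 1.47 ± 0.13. Nitrate assimilation genes rose in 7 of 15 cases and fell in 4. Of 11 defence genes 4 rose and 4 fell, with LOX2 up and WRKY33 (-2.44 ± 0.17), JAZ1 (-2.06 ± 0.17) and PDF1.2A (-3.04 ± 0.28) down. The median, the mean and the camera direction differed in sign for 7 lists without a call, the NIGT1 family, nitrate assimilation, nitrogen demand peptides, abscisic acid and cold, defence, xenobiotic response and root tissue markers. Over all probe sets 4874 were higher and 3289 lower of 15922 tested (limma, Benjamini-Hochberg), but among changes of at least 1, 296 were higher and 641 lower. The authors' deposited table called 2131 by Benjamini-Hochberg values and 5720 by q-values.

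In starved roots of the overexpressor, most measured genes of photosynthesis, phosphate and sulfur starvation, cytokinin and nitrogen regulation were lower than in wild type. TGA1, a bZIP factor of the nitrate response, fell by 5.15 ± 0.09 (adjusted p = 2.52e-20). It was followed by UMAMIT17 of the amino acid exporter family (-4.49 ± 0.12), the nicotianamine synthase gene NAS1 (-4.27 ± 0.11), AT4G01390 (-3.99 ± 0.09), NRT2.4 (-3.80 ± 0.12), AT5G37990 (-3.56 ± 0.12), AT4G33720 (-3.22 ± 0.64) and DUR3 (-3.22 ± 0.09). AT4G33720 fell by 2.25 ± 0.56 without the first overexpressor array and by 4.0 ± 0.63 without the third. TGA1 and NAS1 did not rise in VP roots, where the differences were -0.23 ± 0.09 and -0.22 ± 0.11. Besides NIGT1.2 (5.86 ± 0.06), the largest rises were those of the immune regulators CBP60G (3.13 ± 0.10) and FMO1 (2.54 ± 0.11), AT5G38910 (2.66 ± 0.13), BOR5 (2.42 ± 0.12), the cutinase gene CDEF1 (2.37 ± 0.10), the cell wall invertase gene CWINV5 (2.17 ± 0.17) and AT2G37870 (1.77 ± 0.13).

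NIGT1.1 (-1.93 ± 0.07), NIGT1.3 (-3.0 ± 0.08) and NIGT1.4 (-3.03 ± 0.10) fell in overexpressor roots. NRT2.5 fell by 1.79 ± 0.12, NPF6.3 by 1.71 ± 0.06, NRT2.1 by 0.59 ± 0.13, NIA1 by 0.52 ± 0.11 and NIR1 by 0.22 ± 0.06, while NIA2 rose by 0.17 ± 0.05.

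Photosynthesis genes fell in 25 of 26 cases in overexpressor roots, with LHCB3 at -2.80 ± 0.07, GAPA at -2.94 ± 0.09 and LHCB5 at -2.39 ± 0.07 (adjusted p = 5.16e-27, and adjusted p = 0.0151 with an estimated correlation). They also fell in 20 of 26 cases in mock-treated VP roots against sufficient wild type. Phosphate starvation genes fell in 15 of 23 cases and rose in 2, with the sulfolipid synthase gene SQD2 at -2.1 ± 0.10 and the phosphate exporter gene PHO1 at -0.96 ± 0.05 (adjusted p = 5.29e-09, and adjusted p = 0.0151 with an estimated correlation). Cytokinin genes fell in 14 of 20 cases and rose in 2, with LOG7, an enzyme of cytokinin activation, at -2.05 ± 0.07 and CYP735A2 at -2.01 ± 0.10 (adjusted p = 8.3e-08, and adjusted p = 0.00571 with an estimated correlation). Sulfur starvation genes fell in 9 of 11 cases and rose in 1, with APR1 at -1.50 ± 0.08 and LSU2 at -1.94 ± 0.11 (adjusted p = 7.17e-07, and adjusted p = 0.0197 with an estimated correlation). Nitrogen regulators fell in 9 of 16 cases and rose in 0, or 1 adjusted over the list alone, with LBD38 at -1.15 ± 0.07 and LBD37 at -1.05 ± 0.07 (adjusted p = 0.000125, and adjusted p = 0.0151 with an estimated correlation). These 5 calls held with an estimated correlation.

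Another 5 lists were called in overexpressor roots only with the preset correlation. Nitrate assimilation genes fell in 11 of 15 cases and rose in 1, with RFNR2 at -0.98 ± 0.05 (adjusted p = 2.5e-05, and adjusted p = 0.101 with an estimated correlation). Flavonoid genes fell in 10 of 15 cases and rose in 1 (adjusted p = 0.000523, and adjusted p = 0.0828 with an estimated correlation). Nitrate transport genes fell in 10 of 25 cases and rose in 5, or 11 and 5 adjusted over the list alone, with NPF7.3 at -1.64 ± 0.05 and NRT2.2 at -2.58 ± 0.11 (adjusted p = 0.00122, and adjusted p = 0.0828 with an estimated correlation). Glutamine and glutamate metabolism genes fell in 7 of 15 cases and rose in 2, or 7 and 3 adjusted over the list alone, with the glutamate dehydrogenase gene GDH3 at -3.12 ± 0.11 and GLN1;4 at -2.29 ± 0.10 (adjusted p = 0.00185, and adjusted p = 0.0828 with an estimated correlation). The NIGT1 family fell in 4 of 7 cases, or 5 adjusted over the list alone, and rose in 1, the overexpressed NIGT1.2 (adjusted p = 0.00195, and adjusted p = 0.101 with an estimated correlation). Ammonium, urea and amino acid transporters, without a call, rose in 2 of 15 cases and fell in 5, with a median and a mean of different sign. Over all probe sets 3412 were higher and 2658 lower of 15922 tested (limma, Benjamini-Hochberg), but 68 and 351 among changes of at least 1. The authors' deposited table called 990 by Benjamini-Hochberg values and 2519 by q-values.

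Induction of AtNIGT1.2-VP for 24 h raised most measured genes of phosphate starvation, defence and glutamine and glutamate metabolism in shoots kept on sufficient nitrogen. DIN11, a dark-inducible gene of the dioxygenase family, rose by 6.23 ± 0.18 (75.1-fold, adjusted p = 7e-13), GDH3 by 5.63 ± 0.15, RNS1 by 5.42 ± 0.20 and the phosphatase gene PS2 by 5.26 ± 0.18. The defensin gene PDF1.2A rose by 5.25 ± 0.28, the acyltransferase gene AACT1 by 5.22 ± 0.22, the acid phosphatase gene PAP24 by 5.12 ± 0.13 and the glutathione transferase gene GSTU4 by 4.93 ± 0.18. Falls were smaller: ORA47 fell by 2.59 ± 0.30, GSTF11 by 2.24 ± 0.14, MYB77 by 2.1 ± 0.11, AT1G65490 by 2.07 ± 0.18, AT1G73120 by 2.06 ± 0.20, AT4G19430 by 2.03 ± 0.45, CYP81D11 by 1.98 ± 0.17 and AT1G13650 by 1.97 ± 0.14.

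NIGT1.4 rose by 2.99 ± 0.17 in induced shoots, NRT2.4 by 2.05 ± 0.12, NRT2.5 by 1.41 ± 0.19, NPF6.3 by 0.47 ± 0.13 and NIA2 by 0.30 ± 0.07, and NIR1 fell by 0.27 ± 0.10, a call lost when any 1 of 4 arrays was left out (adjusted p = 0.0682 to 0.0911). NIGT1.3, below the filter on mean level, changed by 3.24 ± 0.19 (adjusted p = 8.44e-10 with no filter). NIGT1.1 (-0.06 ± 0.20), NRT2.1 (-0.01 ± 0.28) and NIA1 (0.23 ± 0.17) did not pass the test.

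Phosphate starvation genes rose in 13 of 23 cases in induced shoots and fell in 3, or 14 and 3 adjusted over the list alone, with PAP17 at 4.01 ± 0.16 and GDPD1 at 2.04 ± 0.10 (adjusted p = 2.2e-05, and adjusted p = 0.0296 with an estimated correlation). Defence genes rose in 10 of 11 cases, with LOX2 at 2.5 ± 0.14 and the camalexin synthesis genes PAD3 at 4.52 ± 0.38 and CYP71A13 at 2.61 ± 0.23 (adjusted p = 1.89e-06, and adjusted p = 0.0296 with an estimated correlation). Glutamine and glutamate metabolism genes rose in 10 of 16 cases and fell in 0, with GLN1;4 at 3.26 ± 0.16 and GLN1;1 at 1.35 ± 0.11 (adjusted p = 0.00058, and adjusted p = 0.0447 with an estimated correlation). These 3 calls held with an estimated correlation. Ammonium, urea and amino acid transporters rose in 10 of 16 cases and fell in 4, with the ammonium transporter gene AMT1;4 at 3.53 ± 0.09 and DUR3 at 4.92 ± 0.16 (adjusted p = 0.0137, and adjusted p = 0.31 with an estimated correlation). Senescence and autophagy genes rose in 12 of 21 cases and fell in 1, with SAG21 at 1.36 ± 0.10 and ORE1 at 1.92 ± 0.20 (adjusted p = 0.000963, and adjusted p = 0.354 with an estimated correlation). The NIGT1 family rose in 3 of 6 cases, NIGT1.2 with its transgene included, with HHO5 at 1.61 ± 0.13 (adjusted p = 0.018, and adjusted p = 0.344 with an estimated correlation). Lists without a call included nitrate transport (7 of 24 rose, 7 fell), sulfur starvation (1 of 9 rose, 6 fell, or 2 and 6 adjusted over the list alone) photosynthesis (0 of 29 rose, 10 fell) and starch and sugar (3 of 7 rose, 2 fell, or 3 and 3 adjusted over the list alone), whose median and mean differed in sign. Over all probe sets 3792 were higher and 4056 lower of 15922 tested (limma, Benjamini-Hochberg), 585 and 216 of them by at least 1, and the authors' deposited table called 2751 by Benjamini-Hochberg values and 7559 by q-values.

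In induced roots, most measured genes of ammonium and amino acid transport and of phosphate starvation rose, with all 7 of the NIGT1 list, while nitrate transport genes moved both ways. The glutamate dehydrogenase gene GDH3 rose by 7.12 ± 0.11 (139-fold, adjusted p = 1.63e-21), AT4G37220 by 6.83 ± 0.12 and NRT2.4 by 6.72 ± 0.12 (105-fold, adjusted p = 6.24e-21). The trehalose phosphate phosphatase gene TPPC rose by 6.19 ± 0.10, AT2G04460 by 6.18 ± 0.08, RNS1 by 6.08 ± 0.09, the carboxylesterase gene CXE17 by 5.39 ± 0.10 and AMT1;4 by 5.30 ± 0.11. The deepest falls were those of AT2G43590 (-2.74 ± 0.10), AT5G14650 (-2.65 ± 0.14) and the cell wall genes XTH17 (-2.41 ± 0.11) and EXPA17 (-2.17 ± 0.11). The lipid transfer-like gene AZI1 (-2.32 ± 0.13), the tonoplast channel gene TIP2;3 (-2.13 ± 0.12), AT1G19900 (-2.07 ± 0.17) and AT1G51860 (-2.06 ± 0.10) followed. NIGT1.1, NIGT1.3 and NIGT1.4 rose by 1.84 ± 0.07, 3.48 ± 0.08 and 1.51 ± 0.10. NRT2.5 rose by 4.72 ± 0.12, NIA1 by 0.60 ± 0.11, NIA2 by 0.53 ± 0.05 and NPF6.3 by 0.22 ± 0.06. NRT2.1 fell by 0.72 ± 0.13 and NIR1 by 0.33 ± 0.06.

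All 7 NIGT1 family genes rose in induced roots, NIGT1.2 with its transgene included (adjusted p = 3.42e-12, and adjusted p = 0.00425 with an estimated correlation). Phosphate starvation genes rose in 17 of 23 cases and fell in 1, with PAP17 at 4.70 ± 0.10, SPX1 at 4.38 ± 0.13 and the galactolipid synthase gene MGD2 at 3.35 ± 0.10 (adjusted p = 9.91e-15, and adjusted p = 0.00425 with an estimated correlation). Ammonium, urea and amino acid transporters rose in 12 of 15 cases and fell in 2, with DUR3 at 3.54 ± 0.09 and AMT1;1 at 1.48 ± 0.05 (adjusted p = 7.43e-09, and adjusted p = 0.00425 with an estimated correlation). Glutamine and glutamate metabolism genes rose in 8 of 15 cases and fell in 2, or 9 and 3 adjusted over the list alone, with GLN1;4 at 5.11 ± 0.10 (adjusted p = 1.07e-05, and adjusted p = 0.0287 with an estimated correlation). These 4 calls held with an estimated correlation.

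Nitrogen demand peptide genes rose in 4 of 8 cases in induced roots and fell in 1, with CEPD1 at 4.84 ± 0.16 (adjusted p = 0.00975, and adjusted p = 0.13 with an estimated correlation). Photosynthesis genes fell in 17 of 26 cases, or 18 adjusted over the list alone, and rose in 1, PSAD2, at 2.86 ± 0.11 (adjusted p = 0.000472, and adjusted p = 0.444 with an estimated correlation). Root tissue markers fell in 3 of 5 cases, with the peroxidase genes PER57 at -0.95 ± 0.05 and PER27 at -1.03 ± 0.07 (adjusted p = 0.0113, and adjusted p = 0.269 with an estimated correlation). Flavonoid genes fell in 9 of 15 cases and rose in 2, with F3H at -1.03 ± 0.09 (adjusted p = 0.0127, and adjusted p = 0.255 with an estimated correlation). Cytokinin genes, without a list call, rose in 5 of 20 cases and fell in 12, with the cytokinin activation genes LOG1 (2.63 ± 0.12) and LOG7 (2.39 ± 0.07) up and CKX4 (-1.91 ± 0.09) down. The median and the mean differed in sign for nitrate assimilation, nitrogen regulators and senescence, none of them called. Over all probe sets 2484 were higher and 4503 lower of 15922 tested (limma, Benjamini-Hochberg), 435 and 250 of them by at least 1, and the authors' deposited table called 3395 by Benjamini-Hochberg values and 6843 by q-values. An estradiol-treated wild type was not analysed here, so a response to estradiol itself is not separated from that to the fusion in either tissue.

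**Figure D2:**
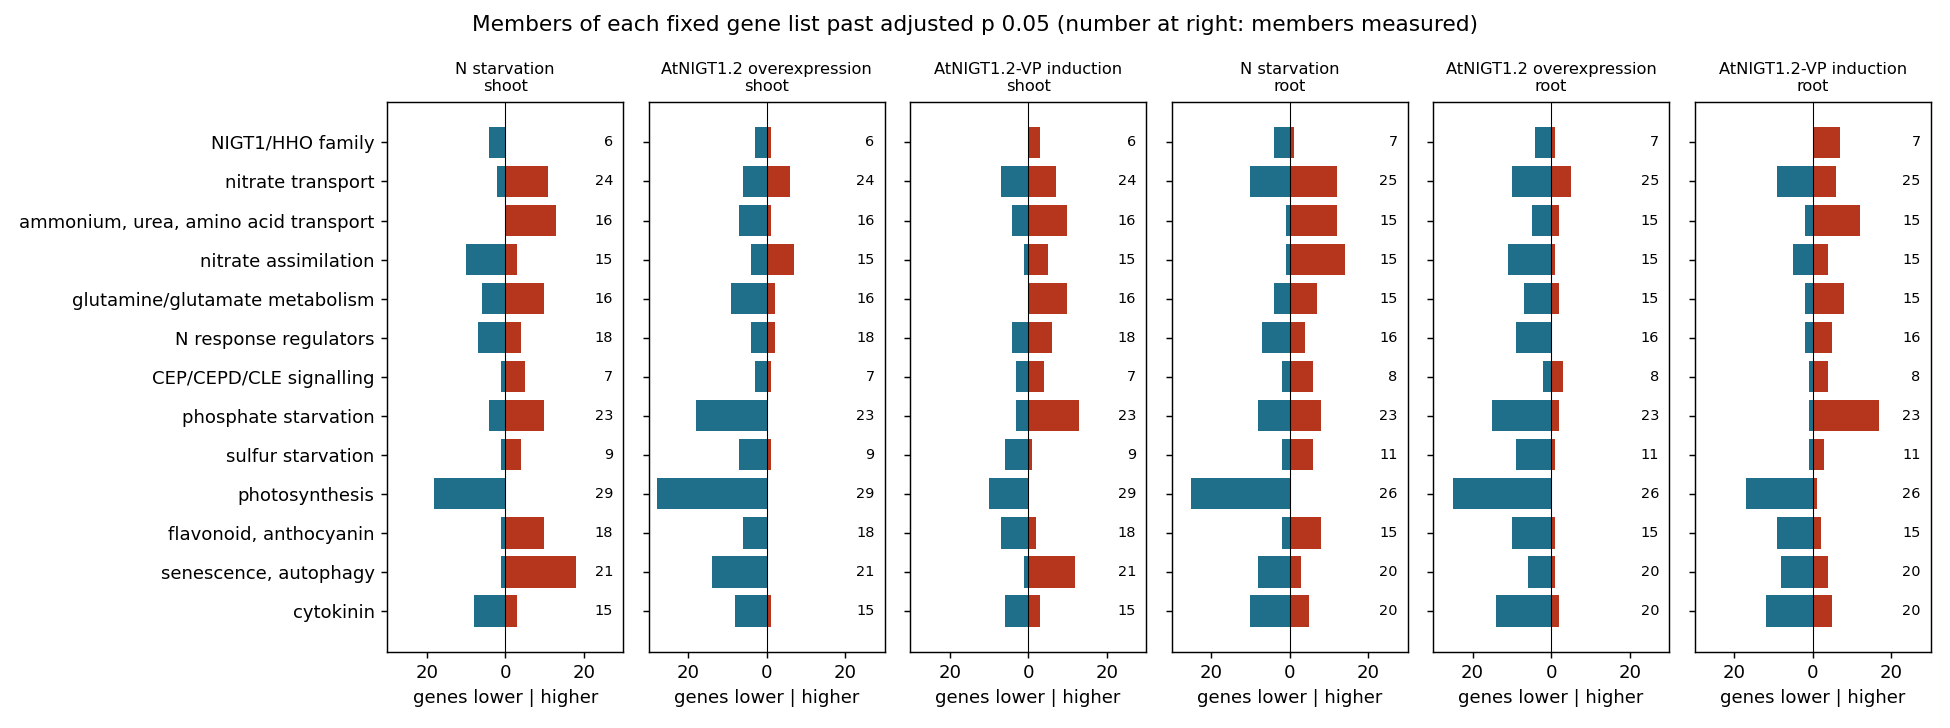
Number of members of 13 gene lists past an adjusted p of 0.05 in each comparison, lower to the left (blue) and higher to the right (red), with the number measured at the right of each panel. Phosphate starvation genes fell in 18 of 23 cases in overexpressor shoots and rose in 17 of 23 in induced VP roots.

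The mock-treated VP line was compared with sufficient wild type as a background. In shoots 2812 probe sets were higher and 2513 lower, 84 and 183 of them by at least 1. In roots 1922 were higher and 971 lower, 22 and 34 of them by at least 1; the total of 2893 fell to 1612 without the first mock array. All 6 xenobiotic response genes were lower in mock-treated shoots, with GSTU24 at -1.34 ± 0.16, and 6 of 7 were lower in roots, with UGT74E2 at -1.41 ± 0.08. Defence genes were lower in 10 of 11 cases in shoots, with PR1 at -1.81 ± 0.31. In roots NIA1 was higher by 1.86 ± 0.11 and 10 of 15 nitrate assimilation genes were higher. NIGT1.4 was lower by 0.75 ± 0.17 in shoots, and in shoots no other of the genes followed throughout passed the test. In roots NRT2.1 (0.47 ± 0.13), NPF6.3 (0.43 ± 0.06), NIR1 (0.44 ± 0.06) and NIA2 (0.17 ± 0.05) were higher; without the first mock array NRT2.1 and NIA2 did not pass (adjusted p = 0.134 and 0.0883), nor without some of the wild type arrays. The lines also differed in the age at transfer, 9 against 7 days.

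The series was designed to find direct targets of AtNIGT1.2, for which genes lower in the overexpressor and higher with AtNIGT1.2-VP were counted. In shoots, 12 genes moved that way by the largest margin: DUR3, RNS1, GLN1;4, PDF1.2A, AT2G17710, MAPKKK19, THA1, PAP17, PFA-DSP3, WRKY46, NAC019 and GDPD5. In roots they were NRT2.4, DUR3, GDH3, NIGT1.3, IGMT2, G3Pp1, GLN1;4, AT2G17710, SQD2, LOG7, APC2 and NIGT1.1. The kinase gene MAPKKK19 moved by -2.26 ± 0.20 in the overexpressor and 3.13 ± 0.20 with the fusion, the threonine aldolase gene THA1 by -2.16 ± 0.21 and 2.16 ± 0.21, the phosphatase gene PFA-DSP3 by -2.05 ± 0.15 and 3.74 ± 0.15, and NAC019 by -2.74 ± 0.37 and 2.01 ± 0.37. In roots IGMT2, an indole glucosinolate methyltransferase gene, moved by -2.81 ± 0.15 and 4.53 ± 0.15, the glycerol-3-phosphate permease gene G3Pp1 by -2.45 ± 0.10 and 3.09 ± 0.10, and APC2 by -2.00 ± 0.09 and 1.98 ± 0.09.

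In roots 774 genes were lower in the overexpressor and higher with the fusion, against 399 for independent lists of those sizes (exact hypergeometric p = 1.02e-96), and 67 changed by at least 1 in both comparisons against 9.01. In shoots the count was 636, fewer than the 746 of independent lists (exact hypergeometric p = 1.00 for an excess), but among changes of at least 1 it was 65 against 22.8 (exact hypergeometric p = 1.48e-14). Shoot genes also moved the same way in both comparisons, with 1490 higher in both against 1082 and 1350 lower in both against 826. Among changes of at least 1, 50 were higher in both against 9.98 (exact hypergeometric p = 1.61e-21) and 62 lower in both against 8.64 (exact hypergeometric p = 2.83e-36), larger ratios than that of opposite changes. In roots 814 were lower in both against 725, but 357 were higher in both against 514. There 1203 were higher in the overexpressor and lower with the fusion, against 933. Among root changes of at least 1, every direction exceeded independent lists. Besides the 67 against 9.01, 7 were higher in both against 1.72 and 16 lower in both against 5.15. Another 8 were higher in the overexpressor and lower with the fusion, against 0.982. Across genes, fold changes in the overexpressor and with the fusion correlated at r = 0.12 in shoots and -0.17 in roots, where genes are not independent replicates. Of the genes tested in both tissues, 192 were lower in the overexpressor and higher with the fusion in shoots and in roots alike, against 29.8 for independent lists (exact hypergeometric p = 2.68e-108). For 17 of them every change was at least 1: PPCK1, NRT2.5, AT1G13750, RNS1, AT2G17710, HIR2, PFA-DSP3, PAP17, G3Pp1, EDA39, SR1, LOG7, GLN1;4, SPX1, MGD2, DUR3 and APK4. Of phosphate starvation genes 11 of 23 moved that way in shoots against 0.969 by chance, the largest share of any list there, and 12 of 23 in roots against 1.18. In roots the NIGT1 family had a larger share, 4 of 7 against 0.359. Senescence and autophagy genes gave 8 of 21 in shoots and 0 of 20 in roots.

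**Figure D3:**
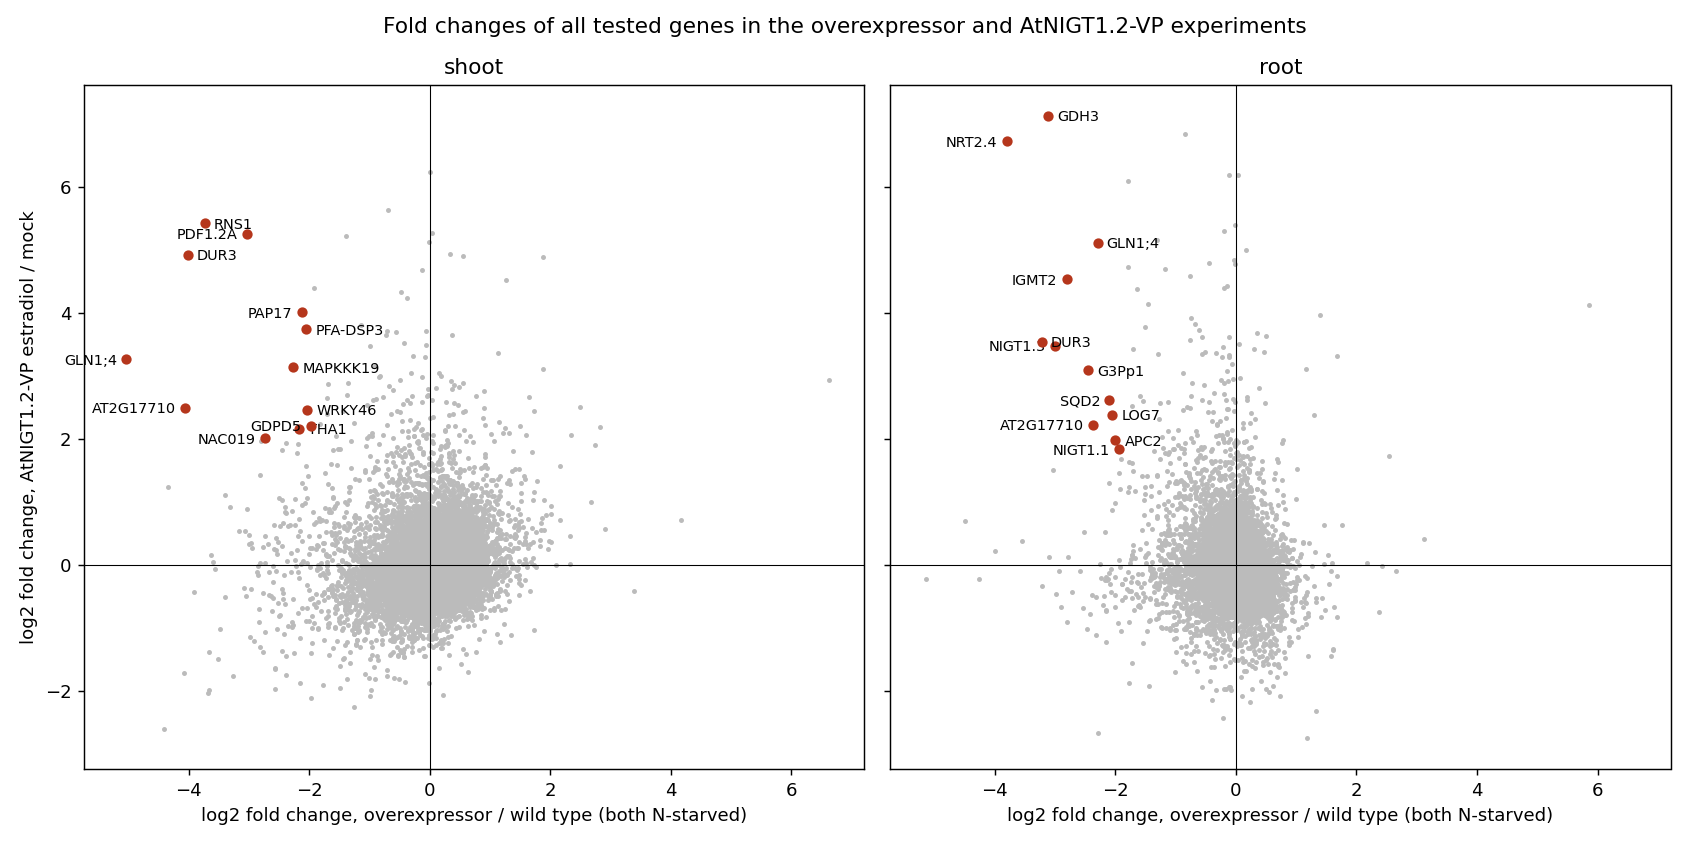
Log2 fold change of each tested gene in the overexpressor against wild type (x axis) and with estradiol against mock in the AtNIGT1.2-VP line (y axis), in shoots and roots, with the 12 genes of largest margin per tissue in red. DUR3 lay at -4.02 and 4.92 in shoots and at -3.22 and 3.54 in roots.

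Genes raised by nitrogen starvation were compared with both transgenic responses. Among 4203 genes higher in starved shoots and 3176 lower in the overexpressor, 1254 were shared, against 884 for independent lists (exact hypergeometric p = 2.54e-58), and in roots 1054 against 841 (exact hypergeometric p = 1.88e-22). NRT2.4 and GLN1;4 in roots and DUR3 in both tissues were among them. Genes lower in both comparisons were also more than expected, 972 against 848 in shoots and 794 against 548 in roots (exact hypergeometric p = 3.16e-36). Among changes of at least 1, genes raised by starvation and lower in the overexpressor were 187 against 30.3 in shoots and 72 against 8.27 in roots, and genes lower in both were 26 against 19.6 (exact hypergeometric p = 0.0857) and 67 against 8.77. These comparisons share the 3 starved wild type arrays of each tissue. Simulated unchanged groups against those arrays shared 0 genes. They held no true changes, so this count does not measure what shared arrays add to an overlap of called genes. The covariance of fold changes was -0.0481 against a simulated -0.00766 in shoots and 0.000741 against -0.00401 in roots. The 3 control arrays cannot be split, and part of the excess may come from them. With the fusion, which shares no array with the starvation comparison, 1893 genes were higher in both in shoots against 987 for independent lists (exact hypergeometric p = 7.04e-306), and 1093 in roots against 792 (exact hypergeometric p = 1.69e-44). The excess was not limited to rises, since 2057 genes were lower in both in shoots against 1048, and 1157 in roots against 938. Opposite changes were fewer than expected, except genes raised by starvation and lower with the fusion in roots, 1514 against 1439. This depletion did not hold among changes of at least 1. There, genes raised by starvation and lower with the fusion were 14 against 10.1 in shoots and 21 against 6.08 in roots. Those lowered by starvation and higher with the fusion were 28 against 17.1 and 17 against 11.3. Genes higher in both were 161 against 26.5 and 53 against 10.6, and genes lower in both 46 against 6.49 and 40 against 6.45. Fold changes with the fusion and with starvation correlated across genes at r = 0.36 in shoots and 0.15 in roots.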

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

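In 35 cases a named gene or list member moved one way in all shoot arrays and the opposite way in all root arrays under the same comparison. The difference was not tested, because the tissues were treated as normalized separately. The cases include the reference genes UBQ10, ACT8 and ACT2, so opposite shifts as small as theirs need not mark a response to the treatment. Each gene is followed by its log2 fold change in shoots and then in roots.

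With nitrogen starvation of wild type, 5 genes of the nitrate assimilation list and 1 of sulfate reduction fell in shoots and rose in roots: NIA1 (-2.43 and 2.46), NIA2 (-0.50 and 0.91), NIR1 (-1.66 and 0.83), G6PD3 (-1.17 and 1.38), UPM1 (-1.09 and 0.73) and APR2 (-0.42 and 0.72). Genes of several other lists rose in shoots and fell in roots: NAP (2.24 and -0.36), PAO (1.18 and -0.39), SAG21 (0.48 and -0.85), RD29A (1.71 and -0.87), COR47 (0.50 and -0.15), CYP81D11 (1.06 and -1.0) and PAP17 (1.5 and -0.67). The same held for the nitrate transporter gene NPF7.3 (1.45 and -1.06), MLP328 (1.61 and -0.29), CLV1 (0.29 and -0.67) and UBQ10 (0.35 and -0.28).

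In the overexpressor, the immune regulator CBP60G (-1.34 and 3.13), NIA2 (-0.86 and 0.17) and WRKY6 (-0.23 and 0.39) were lower in shoots and higher in roots, and GLT1 (0.52 and -0.38) and PGD3 (0.48 and -0.28) the reverse. With AtNIGT1.2-VP, AT2G43590 (0.95 and -2.74), ORE1 (1.92 and -0.51), F6'H1 (1.82 and -0.33), WRKY6 (0.64 and -0.57), SULTR1;2 (0.46 and -0.56), CEPR2 (0.63 and -0.37), ACT8 (0.26 and -0.31) and ACT2 (0.21 and -0.12) were higher in shoots and lower in roots. GSTF11 (-2.24 and 0.65), CEPH (-0.62 and 1.68), APR1 (-0.62 and 1.23), APR2 (-1.14 and 0.26) and APR3 (-0.59 and 0.74) were lower in shoots and higher in roots.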

How the results depend on the processing

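The alternatives were chosen before the data were examined, except the authors' deposited tests, which were added after seeing the data. Over 24 results, 306 of 328 comparisons with an alternative stayed within the range set for each kind of result and 22 moved. Most results are counts, which cannot reverse. Only the log2 fold changes of the AtNIGT1.2 transcript, which the transgenes raise, could have, and 0 reversed. Requiring a log2 fold change of at least 1 left 1259, 937, 801 and 267 probe sets for nitrogen starvation, overexpression, AtNIGT1.2-VP and the background comparison in shoots and 841, 419, 685 and 56 in roots, fewer by construction. The authors' deposited tests called 2868, 2131 and 2751 for the first 3 comparisons in shoots and 2533, 990 and 3395 in roots by their Benjamini-Hochberg values. Their q-values under 0.05 gave 8377, 5720 and 7559 in shoots and 8380, 2519 and 6843 in roots, nearer to the counts given here in all 6. For nitrogen starvation the q-values called more than the unadjusted p-values under 0.05 did, 8268 in shoots and 7843 in roots; how they were made is not given in the sources used here. With an estimated correlation in camera, 0, 1 and 3 lists were called in shoots, against 10, 8 and 6, and 1, 5 and 4 in roots, against 7, 10 and 8. The background comparison in roots gave 1847 probe sets with only its 2 groups in the fit, against 2893, and 1612 to 3086 in leave-one-out fits, lowest without VP mock replicate 1; the cause was not tested. The replicate block moved results by 0.929 to 1.14 times, to 8378 probe sets for nitrogen starvation in shoots and 6032 for overexpression in roots, for example. Arrays sharing a replicate number did not deviate together: over 24 pairs r ran from -0.46 to 0.18, 7 were best matches, and in 0 of 8 comparisons were all pairs above 0.1. The pseudocount alternatives did not apply, since the values were on a log scale, and an effect of tissue on a response was not tested. Signal over background could not be measured from the files used here.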

Other observations

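The tests in this part were chosen after the results were seen, except the time of harvest, the level before induction and the splits of the arrays. The wound and touch list, and the clock genes named next, were also chosen after their values were seen.

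Clock transcripts set the transgenic shoots apart from wild type. CCA1, a morning-phased clock factor, had a mean level of 8.01 in starved and 7.45 in sufficient wild type shoots, against 5.15 in the overexpressor, 5.45 in mock-treated and 5.29 in induced VP shoots. LNK1 fell by 1.53 ± 0.09 and LNK2 by 1.32 ± 0.11 in the overexpressor, and by 0.38 ± 0.09 and 1.08 ± 0.11 in mock-treated VP shoots against sufficient wild type. Evening-phased TOC1 was higher by 0.78 ± 0.11 and 0.72 ± 0.11 in these comparisons, PRR3 by 1.37 ± 0.14 and 1.1 ± 0.14, COR27 by 2.15 ± 0.14 and 1.22 ± 0.14, and JMJD5 by 2.91 ± 0.14 and 2.58 ± 0.14.

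Early wound and touch transcripts fell together in overexpressor shoots, 15 of 15 with a median of -2.91. They were chosen for this fall, so the count does not test it. ORA47 fell by 4.41 ± 0.30, WRKY40 by 3.60 ± 0.19, ERF6 by 3.40 ± 0.13 and ZAT10 by 2.99 ± 0.25. With nitrogen starvation of wild type 13 of 15 rose and 0 fell, with a median of 1.15; WRKY40 rose by 2.19 ± 0.19 and ZAT10 by 2.07 ± 0.25. The genes were chosen for a fall measured against the same 3 starved arrays, which favours a rise here, so the 2 counts are not independent. With AtNIGT1.2-VP 9 fell and 2 rose, and in mock-treated VP shoots 2 were lower. In roots 2 of 11 fell and 1 rose in the overexpressor.

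The clock difference was weighed first. Lists of morning and evening genes not looked at before were used: the evening median minus the morning median was 1.2 in overexpressor shoots and 0.749 in mock-treated VP shoots against wild type, where harvest at different times of day was predicted to give more than 0.5. In overexpressor shoots it came from the morning list, with a median of -1.20 against 0.0013 for the evening list. Of 8 evening genes there, 3 were higher and 1 lower. In mock-treated VP shoots the medians were -0.47 for morning and 0.28 for evening genes. In roots the difference was 0.644 and 0.416. Root morning medians were -0.39 in the overexpressor and -0.38 in mock, and evening medians 0.26 and 0.034. In mock roots 0 of 8 evening genes passed the test. The difference also reached 0.518 in shoots and 0.497 in roots between estradiol and mock within the VP line, so a value near 0.5 does not single out the line or the time of harvest. Of 6 genes of these lists past the threshold in both shoot comparisons, 1, PHS2, moved opposite ways and 5 the same way. This argues against AtNIGT1.2 acting directly on the set with a leaky VP fusion of opposite action, but not for PHS2 alone, nor against a fusion of like action. The bound was moved, after the value was known, from 0 genes moving opposite ways to fewer than move the same way. By the first bound the explanation would stay open. No leak was seen in the AtNIGT1.2 transcript of mock-treated VP shoots, which differed from sufficient wild type by -0.20 ± 0.25. That standard error is shared by all 5 groups, of which starved wild type had an SD of 0.84. The mock arrays, at 9.56 ± 0.08 (SD), all lay below those of sufficient wild type, at 9.77 ± 0.11 (SD). The probe set does not tell the transgene from the endogenous transcript, so a small leak is not excluded. In roots the transcript was 0.28 ± 0.06 higher in mock. Harvest at different times of day may explain part of the pattern, but the labels give no time of harvest, and age at transfer in the VP line and other effects of the transgenes stay open, untested.

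Second, of 325 genes lower by at least 1 in overexpressor roots, 121 rose with AtNIGT1.2-VP and 204, TGA1 among them, did not. Signal at the top of the array scale is argued against, since the median mock level of the 204 lay 5.27 below the highest level. A gene disrupted by the inserted transgene, with effects on others, stays open and was not tested. A high level before induction could not be decided (Spearman rho = -0.260 across genes between sufficient level and change with the fusion). Indirect lowering over 3 days without nitrogen stays open and was not tested.

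As the last pattern, photosynthesis genes fell in overexpressor roots. Green tissue carried into the wild type root samples would need a share of 0.226% for PRK to 4.38% for LHCA4 to give the difference between wild type and overexpressor roots. A saturated shoot signal would raise that share, so members at 13 or more in shoots were left out, and the other 13 needed a median of 1.03%. Of 149 transcripts abundant in shoots, 5 lay in roots under 1 part in 2 of what this share would bring, and 4 did so by 2 standard errors, where at least 5 were asked for, so green tissue stays open. This form was set after an earlier one, with all 25 members, a median of 1.86% and no standard errors, had given 12 and so argued against green tissue. Both forms divide root values by shoot levels, and the tissues were treated as normalized separately. If the fusion raises the targets of AtNIGT1.2, which the labels do not state, direct repression by AtNIGT1.2 is argued against, since the 25 members lower in the overexpressor had a median of -0.46 with the fusion, 1 higher, 17 lower and 7 not passing. Without that assumption direct repression stays open. An indirect effect of the transgene on root greening stays open and was not tested.

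Arrays were also split in other ways. Groups of 3 and 3 give 10 splits, too few for a share under 0.05. Every split but the real one mixes the 2 groups. Where the groups differ, this widens the spread and lowers the calls of probe sets, so the counts of probe sets decide nothing. For probe sets changed, 1 of 10 splits, the real one, gave as many in each comparison: in shoots 8615 against at most 0 in other splits for nitrogen starvation, 8163 against 15 for overexpression, 7848 against 144 for AtNIGT1.2-VP and 5325 against 0 for the background; in roots 8731 against 0, 6070 against 17, 6987 against 0 and 2893 against 0. For called lists in shoots, 1 of 10 splits gave as many for nitrogen starvation (10 against 7), 3 for overexpression (8 against 11) and 1 for AtNIGT1.2-VP (6 against 4). In roots the splits were 2 (7 against 7), 3 (10 against 12) and 3 (8 against 8) of 10. Except for nitrogen starvation and AtNIGT1.2-VP in shoots, other splits thus called as many lists or more at the preset correlation. The other splits mix the 2 groups unevenly and so keep part of the real difference. Lists called in them therefore do not measure chance, and these counts do not decide whether the list calls are real. For genes shared by a pair of comparisons, 1 of 100 splits, the real one, gave as many. For the 2 pairs without shared arrays this decides nothing, since other splits called fewer probe sets than the real overlap. The counts lower in the overexpressor and higher with the fusion were 636 against at most 12 in shoots and 774 against 1 in roots. For genes higher with both starvation and the fusion they were 1893 against 10 and 1093 against 0. For genes higher with starvation and lower in the overexpressor they were 1254 against 728 and 1054 against 497. These draws of the 9 arrays mix groups that differ, which widens the spread and lowers the calls. They therefore do not test the excess over independent lists, nor separate an excess from the shared control arrays.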
